A study of Mus musculus with 54 samples.

How the data were processed

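Poly(A) RNA from liver, kidney and quadriceps of male and female C57BL/6J mice was sequenced as stranded 150 bp paired-end libraries, per the labels' protocols. Per the submitters' processing notes, reads were handled with fastp 0.20.0, FastQC 0.11.9, HISAT2 2.1.0 and featureCounts 2.0.1, with genome build GRCm38 (mm10). The strand setting of the counting, the annotation release and the tool behind the authors' own comparisons are not given in the sources used here. Overlapping and antisense genes and near-identical paralogs, such as the Cyp2b, Serpina1, Orm and Bhmt families, are therefore reported with the uncertainty that the authors' counting could have split their reads.

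The deposited tables, 1 per tissue, hold raw counts per gene and library, TPM values made by the authors, and for 9 comparisons per tissue the authors' log2 fold changes, p-values and adjusted p-values. The deposited counts are whole numbers without normalization, and all tests below start from them. For every gene with at least 100 counts in each library of a tissue, the deposited TPM values imply 1 length per gene within 0.1 percent. They were not used in a test. The authors' log2 fold changes and p-values were used only for counts of their calls. Columns were matched to samples by name, and 0 columns of per-sample values were left without a sample. The series lists 54 samples, and 53 libraries were analysed. Replicate 1 of the liver male corylin group was not analysed here, so that group has 2 libraries. Library names identify the animals: the 53 libraries come from 18 animals, most of which gave all 3 tissues. The names also carry a letter, B in 41 libraries and R in 12, whose meaning is not given. Every young library carries B, and each old and corylin group of 3 holds 2 B and 1 R, and the liver male corylin group 1 of each, so R libraries come from aged mice only. Total counts per library are given as multiples of 1e+06 counts: they ran from 8.69 to 23.19, with a median of 15.49.

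Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 15158 genes in liver, 17174 in kidney and 14173 in quadriceps. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust, TMM normalization) in 1 fit per tissue over its 6 groups, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The fit shares 1 estimate of the spread among the groups of a tissue. The comparisons were corylin against old and old against young in each sex and averaged over the sexes, the difference of each effect between sexes, female against male among young mice, and the difference of the corylin effect between tissues with the animal as a block. Standard errors are of the log2 fold change, from the F statistic. CPM values use TMM library sizes, and log2 CPM a prior count of 2. P-values measure the spread between these samples.

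A total of 50 gene lists was fixed (pathways, stress and immune programs, sex-biased liver genes, and markers of the cell types of these tissues and of tissues that could be mixed in). Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes. This test compares a list with the other genes. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move on balance in one direction, were the alternatives. Changed members are counted by adjustment over all genes and, separately, by adjustment over the list alone. 

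Named genes follow a rule. In each tissue, for corylin against old and old against young in each sex, they are the 5 highest and 5 lowest log2 fold changes among genes with adjusted p under 0.05, average log2 CPM of at least 1 and no overlap between the replicates of the groups, predicted genes left out. Where fewer than 3 passed in a direction, the comparison averaged over sexes gave the missing ones, and where none passed there either, the 3 genes with the smallest p in that direction are given as values only. Each list called by camera, or with at least 2 changed members, adds up to 4 members with the smallest adjusted p and 1 or 2 expected members that did not pass. The sex difference adds the 5 genes with the smallest adjusted p, and Cdkn2a, Cdkn1a, Xist, Kdm5d and Ddx3y serve as checks in every tissue. The lowest ranked were dropped first, and some genes taken by the rule are not reported here. The groups, tests, gene lists and this rule were fixed before the data were examined. A division of the clock list into an activator and an output arm was made afterwards, as were the alternatives named as such in the closing section.

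The gene and list tests were tested on simulated data: counts were drawn from each gene's mean over a tissue's libraries, its dispersion and the real library sizes, with 200 genes changed by known folds. Between 14031 (quadriceps) and 16981 (kidney) genes passed the filter in these draws. For corylin against old in liver, edgeR recovered 31 percent of 2-fold and 87 percent of 4-fold changes in males (5 false calls) and 47 and 83 percent in females (5). In kidney the shares were 64 and 97 percent in males (11 false calls) and 68 and 96 percent in females (11), and in quadriceps 68 and 91 percent in males (6) and 59 and 92 percent in females (8). In the same draws DESeq2 made 26 to 40 false calls per comparison, among 180 to 216 calls, and limma voom 2 to 11. Old libraries enter both the age and the corylin effect, so the correlation between those effects was set beside values simulated for unchanged groups, over 20 draws. No pair of libraries was treated as a duplicate. Alternatives were DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, DESeq2's median-of-ratios size factors within edgeR, no filter on low counts, only the libraries of the groups compared, the library letter as a factor, a block on the replicate number, fry, an estimated list correlation, and leaving out each library in turn. Coordinates are from GENCODE M21 on GRCm38. Python 3.11.15 was used for tables and figures.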

Results

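Gene expression was measured by RNA-seq in liver, kidney and quadriceps of male and female C57BL/6J mice, an inbred laboratory strain, in 3 conditions. Young mice were 50 weeks old, old mice were 130 weeks old and ate a control diet, and corylin mice were 130 weeks old and ate a diet with corylin, a flavonoid of the plant Psoralea corylifolia. Each sex, tissue and condition had 3 libraries, 1 per animal, except for liver of corylin males, which had 2 (replicates 2 and 3). Total counts, in multiples of 1e+06, were 9.03 to 16.61 in liver, 8.69 to 23.19 in kidney and 13.25 to 19.7 in quadriceps. Levels are CPM, counts per 1e+06 counts of a library, given as mean ± SD with n = 3 unless stated. Changes are log2 fold changes ± SE with adjusted p-values from edgeR. A lost call is a gene that passed and did not pass in a fit without 1 library, given as the number of such fits.

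Genes of the sex chromosomes separated the sexes in each tissue. Xist, the RNA that silences an X chromosome, was at 402 ± 33.4 CPM in liver of young females and 0.243 ± 0.198 in young males. Its female over male change among young mice was 10.73 ± 0.29 in liver, 11.20 ± 0.33 in kidney and 10.35 ± 0.42 in quadriceps (edgeR adjusted p = 9.1e-12, 7.56e-13 and 9.84e-10). The Y-linked histone demethylase gene Kdm5d was at 16.9 ± 1.58 CPM in liver of young males and 0 in the 3 female liver groups. The Y-linked helicase gene Ddx3y was at 55.5 ± 24.1 CPM in kidney of young males and 0 in the 3 female kidney groups. In all, 194 genes in liver (80 higher in females, 114 lower), 1073 in kidney (407 higher, 666 lower) and 170 in quadriceps (60 higher, 110 lower) differed between young females and males (edgeR). Cdkn1a and Cdkn2a, cell cycle inhibitors used as markers of senescent cells, did not pass in old against young mice of either sex. Cdkn1a came to 1.14 ± 0.24 in male kidney (edgeR adjusted p = 0.0754) and Cdkn2a to 1.89 ± 0.83 in female liver (0.149). Cdkn2a was tested in liver only. The liver count was 101, 101 and 138 without young male 1, 2 or 3 and 112, 106 and 92 without young female 1, 2 or 3. The kidney count was 640 and 673 without young male 1 or 2 and 615 and 572 without young female 1 or 2. The quadriceps count was 20, 12 and 19 without young male 1, 2 or 3 and 12 and 21 without young female 1 or 2.

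In female liver, age raised genes of the acute phase and immune lists and lowered genes of the fatty acid oxidation list. Of 22 acute phase genes tested, 15 rose and 0 fell (18 and 0 adjusted over the list alone). Among them hemopexin (Hpx), which binds free heme, rose from 3550 ± 552 to 16700 ± 3530 CPM (2.23 ± 0.26, edgeR adjusted p = 0.00191), the orosomucoid gene Orm1 by 2.51 ± 0.38 (0.00458) and ceruloplasmin (Cp) by 2.24 ± 0.37 (0.006). The call of the list was lost with an estimated correlation (adjusted p = 0.242 with an estimated correlation). Macrophage and monocyte markers rose in 15 of 24 cases (20 adjusted over the list alone), with Lyz2 at 2.86 ± 0.63 (edgeR adjusted p = 0.0196) and Gpnmb at 3.28 ± 0.78 (0.0248; adjusted p = 0.242 with an estimated correlation for the list). Neutrophil markers rose in 10 of 12 cases (12 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). Of 26 genes of the unfolded protein and integrated stress response 12 rose and 0 fell (19 and 2 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). Among them were Ddit3 at 1.15 ± 0.20 and Sdf2l1 at 2.77 ± 0.52 (edgeR adjusted p = 0.00684 and 0.0101). Of 27 fatty acid oxidation genes, 9 fell and 0 rose (14 fell and 1 rose adjusted over the list alone; adjusted p = 0.251 with an estimated correlation). They included the acyl-CoA dehydrogenase gene Acadm at -1.26 ± 0.23 and Ehhadh at -1.74 ± 0.32 (edgeR adjusted p = 0.00859 and 0.00876). Calls were lost in 3 of 6 fits for Lyz2 and Gpnmb and 1 for Sdf2l1.

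Among the genes that fell in old female liver were the cytochrome P450 genes Cyp2b13, from 367 ± 55.4 to 2.31 ± 2.78 CPM (-7.30 ± 1.03, edgeR adjusted p = 0.00387), and Cyp2b9, from 613 ± 73 to 14.2 ± 23 CPM (-5.43 ± 1.19, 0.0188). These neighbours on chromosome 7 (Cyp2b13, ENSMUSG00000040583, 26061497 to 26096197 of GRCm38; Cyp2b9, 26173411 to 26210661) belong to a family of similar sequence, so their reads may be split uncertainly. Cyp3a11 fell by 5.28 and the carbonic anhydrase gene Car3 by 5.09 on the log2 scale (SE 1.27 and 1.03, edgeR adjusted p = 0.026 and 0.0139). The call of Cyp3a11 was lost in 5 of 6 fits, and those of Cyp2b9 and Car3 in 1. Without old female 3, Cyp2b9 came to -9.15 and Cyp3a11 to -8.08. Another gene of this superfamily, Cyp3a44, rose by 4.28 ± 0.63 (edgeR adjusted p = 0.00459). In total 1405 genes passed in females (840 higher, 565 lower). The count was 354, 256 and 288 without young female 1, 2 or 3 and 697 and 299 without old female 1 or 2.

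In male liver, 32 genes changed with age (23 higher, 9 lower, edgeR). Hpx rose from 3110 ± 219 to 9720 ± 2200 CPM (1.64 ± 0.25, adjusted p = 0.0236), Orm2 by 5.82 ± 0.97 (0.0334) and the osteoactivin gene Gpnmb by 4.63 ± 0.85 (0.0472). Of 25 male-biased genes 2 fell and 0 rose (12 fell and 0 rose adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). These were the steroid dehydrogenase gene Hsd3b5, from 22 ± 8.69 to 0.272 ± 0.21 CPM (-6.29 ± 0.90, edgeR adjusted p = 0.0236), and the glutathione transferase gene Gstp1 (-1.83 ± 0.29, 0.0236). Of 25 female-biased genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). These were the organic anion transporter genes Slc22a26, from 1.17 ± 0.206 to 29.7 ± 18.6 CPM (4.64 ± 0.53, edgeR adjusted p = 0.00729), and Slc22a27 (2.41 ± 0.44, 0.0425). In old females 6 of the female-biased genes rose and 3 fell (8 and 6 adjusted over the list alone). The difference of the age effect between the sexes passed for 0 genes (edgeR; 1307 at an unadjusted p under 0.05, 143 by DESeq2 and 20 by limma voom). In males calls were lost in all 6 fits for Gpnmb and Slc22a27, 5 for Orm2 and Hsd3b5, 4 for Hpx and Gstp1 and 2 for Slc22a26. The male count was 0, 0 and 6 without young male 1, 2 or 3, and 1 and 5 without old male 2 or 3, against 948 by DESeq2. The count of 0 for the sex difference became 2 without male young 3, 1 without male old 3, female young 2, female old 1 or female old 2, and 27 without female old 3.

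In liver of corylin males compared with old males, 9 genes passed (1 higher, 8 lower, edgeR). Per3, a repressor of the clock (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665, minus strand), rose from 2.75 ± 1.04 to 55.1 ± 20.5 CPM (n = 2) with a change of 4.32 ± 0.51 (edgeR adjusted p = 0.00371), and the clock activator Arntl fell from 18.8 ± 2.54 to 2.19 ± 0.79 CPM (-3.09 ± 0.48, 0.0259). The choline kinase gene Chka fell from 115 ± 15.8 to 28.3 ± 1.76 CPM (-2.02 ± 0.19, edgeR adjusted p = 0.000508) and the mitochondrial protease subunit gene Clpx by 2.35 on the log2 scale (SE 0.34, 0.0174). Of 18 clock genes 1 rose and 1 fell (8 and 5 adjusted over the list alone; adjusted p = 0.684 with an estimated correlation), and Tef, at 1.90 ± 0.34, did not pass (edgeR adjusted p = 0.0582). Of 25 cholesterol synthesis genes 0 passed over all genes (16 rose and 0 fell adjusted over the list alone; adjusted p = 0.684 with an estimated correlation), with Fdft1 at 1.74 ± 0.34 and Msmo1 at 2.42 ± 0.60 (edgeR adjusted p = 0.096 and 0.198). Lost calls numbered 3 of 5 fits for Arntl, 2 for Clpx and 0 for Per3 and Chka. Each of these genes, Per3 and Chka included, lost its call under 2 of the other settings. The count was 4 without old male 2 and 1533 without corylin male 2, where the lone corylin male 3 is assumed to vary like the other groups. H19, a gene of fetal and tumour liver, was at 15.5 ± 21.3 CPM in corylin males (n = 2) and 0.64 ± 0.45 in old males, and corylin male 3 held 30.6 CPM of it. The libraries of this group, corylin males 3 and 2, also lay apart in their scores for the tumour and fetal liver (2.47 and -0.524), neutrophil (3.221 and -1.424), macrophage and monocyte (2.256 and -1.27), cell cycle (1.972 and -0.638) and male-biased lists (-0.391 and 1.943).

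In liver of corylin females compared with old females, 23 genes passed (10 higher, 13 lower, edgeR). Cyp2b13 was 96.5 ± 75.3 CPM against 2.31 ± 2.78 (5.37 ± 0.96, adjusted p = 0.0459). The flagellin receptor gene Tlr5 was 7.64 ± 2.87 against 1.45 ± 0.388 (2.41 ± 0.40, edgeR adjusted p = 0.0319), and the carboxylesterase gene Ces2e 134 ± 40.1 against 50.5 ± 7.04 (1.41 ± 0.23, 0.0319). The tyrosine aminotransferase gene Tat fell from 3080 ± 678 to 1100 ± 195 CPM (-1.48 ± 0.27, edgeR adjusted p = 0.0459), Zpr1 by 1.52 on the log2 scale (SE 0.24, 0.0319) and Serpina1e, from a family of near-identical genes and therefore uncertain, by 3.79 (SE 0.66, 0.0459). Acute phase genes had 0 of 22 over all genes, and 16 fell and 0 rose adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). The fibrinogen gene Fgg was at -1.81 ± 0.34 (edgeR adjusted p = 0.0531). Of 26 genes of the unfolded protein response, 0 passed over all genes and 17 fell and 1 rose adjusted over the list alone (adjusted p = 0.179 with an estimated correlation), Sdf2l1 being at -2.42 ± 0.51 (edgeR adjusted p = 0.0703). Xenobiotic metabolism genes gave 0 of 32 over all genes, and 10 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.364 with an estimated correlation). Old female 3 had a xenobiotic score of -0.034, beside -1.201 and -1.679 in old females 1 and 2 and -0.221 to 0.526 in corylin females. Their MHC class II score was 0.942 to 2.05, above old (0.308 to 0.519) and young females (-1.34 to -0.506). Lost calls numbered 5 of 6 fits for Tat and Serpina1e, 4 for Cyp2b13, Tlr5 and Ces2e and 3 for Zpr1. The count was 6, 1 and 543 without old female 1, 2 or 3 and 78 and 0 without corylin female 1 or 3, and 146 with the library letter in the model. Between the sexes, the corylin effect differed for 0 genes (edgeR; 1033 at an unadjusted p under 0.05, 28 by DESeq2, 0 by limma voom), a count that became 519 without corylin male 2 and 1 without female old 1.

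Averaged over the sexes, 162 liver genes differed between corylin and old mice (78 higher, 84 lower, edgeR), among them the glutathione transferase gene Gstm3 (2.84 ± 0.50, adjusted p = 0.024; 1.61 and 0.0534 without male corylin 3) and Cyp2b13 (4.15 ± 0.82, 0.0307). Their calls were lost in 5 and 7 of 11 fits. The count was 68, 48, 1582 and 374 without male old 1, male old 2, male corylin 2 or male corylin 3, and 65, 678, 30 and 81 without female old 2, female old 3, female corylin 2 or female corylin 3. Age, averaged the same way, gave 2900 genes (1647 higher, 1253 lower), and 1700, 1879, 1852, 1761 and 1828 without male young 2, male young 3, male old 3, female young 2 or female young 3. In female liver the lists of MHC class I genes (3 of 15 rose, 7 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation) and interferon-stimulated genes (9 of 32 rose, 17 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation) rose with age, Gbp3 by 2.1 ± 0.49 (edgeR adjusted p = 0.0234; lost in 4 of 6 fits).

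Old female kidney showed a broad rise of immune, injury and matrix genes. Macrophage and monocyte markers rose in 18 of 20 cases (19 adjusted over the list alone), with the complement genes C1qa, from 24.5 ± 7.84 to 149 ± 16.4 CPM (2.61 ± 0.28, edgeR adjusted p = 8e-05), and C1qb (2.64 ± 0.28, 8e-05). Interferon-stimulated genes rose in 28 of 32 cases (28 adjusted over the list alone; adjusted p = 0.0556 with an estimated correlation), with Oasl1 at 1.98 ± 0.28 and Ifi27l2a at 3.06 ± 0.46 (edgeR adjusted p = 0.000465 and 0.000573). Kidney injury genes rose in 16 of 21 cases (18 adjusted over the list alone), with C3 from 49.2 ± 12.8 to 302 ± 49.5 CPM (2.62 ± 0.25, edgeR adjusted p = 3.96e-05) and Havcr1, the tubular injury marker KIM-1, from 0.747 ± 0.297 to 16.3 ± 8.25 CPM (4.44 ± 0.74, 0.00115). The matrix protease gene Mmp7 rose from 0.236 ± 0.109 to 7.07 ± 1.06 CPM (4.84 ± 0.57, edgeR adjusted p = 0.000144), and 15 of 15 MHC class I genes rose (15 adjusted over the list alone; adjusted p = 0.0556 with an estimated correlation). Extracellular matrix genes rose in 21 of 33 cases (28 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation). The calls of the macrophage list (adjusted p = 0.0182), kidney injury list (0.0182), MHC class II list (8 of 10 rose, 0.0306), acute phase list (9 of 14 rose, 0.0127), inflammation list (21 of 30 rose, 0.0182) and neutrophil list (3 of 5 rose, 0.0306) held with an estimated correlation.

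In old female kidney 543 genes fell. The cystine transporter gene Slc7a13 (chromosome 4, 19818725 to 19842218 of GRCm38) fell from 1.26 ± 0.228 to 0.109 ± 0.00993 CPM (-3.45 ± 0.47, edgeR adjusted p = 0.000309), an old level that rests on few reads. The pyrimidine-degrading enzyme gene Dpys fell from 19.4 ± 2.7 to 1.72 ± 1.06 CPM (-3.45 ± 0.41, 0.000144) and the betaine-homocysteine methyltransferase gene Bhmt, whose reads may be shared with Bhmt1b, from 75.9 ± 12.1 to 5.21 ± 2.78 CPM (-3.86 ± 0.51, 0.000301). Markers of the loop of Henle, distal tubule and collecting duct fell in 5 of 17 cases (9 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation), including Calb1 (-1.16 ± 0.29, edgeR adjusted p = 0.0172; lost in 2 of 6 fits). In total 1863 genes passed in females (1320 higher, 543 lower), and 1057, 1034 and 1225 without young female 2, young female 3 or old female 1. Old female 2 had an adipocyte score of 3.88, beside -0.955 and 0.301 in old females 1 and 3. Of 8 adipocyte markers 1 rose (5 adjusted over the list alone), and the lipid storage gene Lpl was at 1.55 ± 0.37 (edgeR adjusted p = 0.0117), or 0.87 without old female 2 (0.0721).

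In male kidney, 19 genes changed with age (14 higher, 5 lower, edgeR). C3 rose from 19.3 ± 1.7 to 101 ± 31.1 CPM (2.38 ± 0.25, adjusted p = 0.000768), Mmp7 by 4.43 ± 0.77 (0.0422), Serpina3n by 2.79 ± 0.48 (0.0422) and the BMP antagonist gene Grem1 by 3.96 ± 0.68 (0.0422). The aminotransferase gene Aadat fell from 250 ± 15.5 to 138 ± 8.74 CPM (-0.86 ± 0.12, edgeR adjusted p = 0.00967) and Selenbp2 by 1.55 on the log2 scale (SE 0.28, 0.0422). The acute phase list (3 of 14 rose, 9 adjusted over the list alone) held its call with an estimated correlation (adjusted p = 0.00591). Calls were lost in 6 of 6 fits for Grem1, 5 for Mmp7, Serpina3n and Selenbp2, 4 for Aadat and 0 for C3. The sexes differed in the age effect for 16 genes (7 higher and 9 lower in females relative to males, edgeR). The female minus male difference was -3.56 ± 0.53 for Dpys (adjusted p = 0.0217), -4.38 ± 0.68 for Bhmt (0.0266) and 1.07 ± 0.16 for Aadat (0.0217). It was -1.12 ± 0.16 for the lipid enzyme gene Acsl1 and -1.1 ± 0.17 for the cell adhesion gene Nectin1 (edgeR adjusted p = 0.0217 for both). These calls were lost in 7 of 12 fits for Dpys and Bhmt and in 6 for the others. The male count was 2, 1 and 1 without young male 1, 2 or 3 and 30, 1 and 1 without old male 1, 2 or 3, and was 2 with the library letter in the model. The sex-difference count was 0, 0 and 41 without male young 1, 2 or 3, 1 and 0 without male old 2 or 3, 8, 0 and 0 without female young 1, 2 or 3, and 8 and 212 without female old 2 or 3.

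In kidney of corylin males, 12 genes passed (5 higher, 7 lower, edgeR), 4 of them in the clock list. The clock output gene Dbp rose from 9.27 ± 5.39 to 118 ± 33.9 CPM (3.67 ± 0.55, edgeR adjusted p = 0.0132), Per3 from 12.4 ± 3.02 to 54.7 ± 19.4 CPM (2.13 ± 0.33, 0.0132) and Bhlhe41 by 1.69 ± 0.29 (0.0355). The clock repressor Nfil3 fell from 19.6 ± 4 to 4.9 ± 1.57 CPM (-2.02 ± 0.27, 0.00674). Of 18 clock genes 3 rose and 1 fell (9 and 4 adjusted over the list alone; adjusted p = 0.799 with an estimated correlation). Pdk4, a kinase that shifts mitochondria from glucose to fat, fell from 496 ± 42.7 to 153 ± 34.9 CPM (-1.70 ± 0.22, edgeR adjusted p = 0.00583). The lactate transporter gene Slc16a1 fell from 212 ± 6.86 to 56.8 ± 23.1 CPM (-1.89 ± 0.33, 0.0398) and Clpx by 1.01 on the log2 scale (SE 0.15, 0.0109). The epoxide hydrolase gene Ephx1 rose from 69.9 ± 14.6 to 145 ± 27.1 CPM (1.05 ± 0.17, 0.0237). With median-of-ratios scaling 16 passed (5 higher, 11 lower). Calls were lost in 6 of 6 fits for Slc16a1, 5 for Bhlhe41, 4 for Ephx1, 3 for Dbp and Per3, 2 for Clpx, 1 for Nfil3 and 0 for Pdk4. The count was 2, 6 and 3 without old male 1, old male 2 or corylin male 3. It was 23 with the library letter in the model.

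In kidney of corylin females, 10 genes passed (3 higher, 7 lower, edgeR). Slc7a13 rose from 0.109 ± 0.00993 to 2.24 ± 0.324 CPM (4.26 ± 0.43, edgeR adjusted p = 0.000411). The sex difference of the Slc7a13 change was 4.46 ± 0.48 (0.000923), male levels being 496 ± 175 and 430 ± 28.4 CPM. The androgen-regulated protein gene Kap fell from 8460 ± 2730 to 1830 ± 100 CPM (-2.21 ± 0.29, edgeR adjusted p = 0.0039). The lipopolysaccharide-binding protein gene Lbp changed by -1.42 ± 0.20 (edgeR adjusted p = 0.00782) and the immunoglobulin receptor gene Fcgr3 by -1.48 ± 0.24 (0.0302). The matrix protease gene Mmp3 fell from 5.23 ± 0.722 to 1.92 ± 0.386 CPM (-1.45 ± 0.25, 0.0452). Of 32 interferon-stimulated genes 0 passed over all genes (19 fell adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). Of 20 macrophage and monocyte markers 0 passed over all genes (15 fell adjusted over the list alone; adjusted p = 0.152 with an estimated correlation). Of 33 matrix genes 0 passed over all genes (19 fell adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). C1qa was at -1.34 ± 0.27 and Gbp3 at -1.91 ± 0.45 (edgeR adjusted p = 0.0761 and 0.118). Calls were lost in 5 of 6 fits for Mmp3, 2 for Fcgr3, 1 for Kap and Lbp and 0 for Slc7a13. The corylin effect differed between the sexes for 1 gene. The count of 10 was 117 without old female 3, and 30, 5 and 2 without corylin female 1, 2 or 3, and was 31 with the library letter in the model. The sex-difference count was 5, 31 and 3 without male corylin 2, female old 3 or female corylin 1, and 4 with the letter. Averaged over the sexes the corylin count was 11 (7 higher, 4 lower), or 19 (10 higher, 9 lower) with median-of-ratios scaling. It was 5, 6 and 5 without male old 1, male corylin 2 or male corylin 3. It was 4, 38, 20, 27, 5 and 5 without female old 1, 2 or 3 or female corylin 1, 2 or 3. The age count averaged over the sexes was 1522 (1140 higher, 382 lower).

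In old female quadriceps, genes of the interferon and macrophage lists rose and mitochondrial transcripts fell. Interferon-stimulated genes rose in 24 of 29 cases (28 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation), with Gbp2 at 2.39 ± 0.41 (edgeR adjusted p = 0.0161) and Oas2 at 4 ± 0.78 (0.024). Macrophage and monocyte markers rose in 11 of 14 cases (13 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation), C1qa by 3.14 ± 0.64 (edgeR adjusted p = 0.0245) and Cd68 by 4.11 ± 0.85 (0.0245). Without old female 3 these calls were lost, with Oas2 at 2.31, C1qa at 1.72 and Cd68 at 1.82 (edgeR adjusted p = 0.0533, 0.0721 and 0.0612). The cytokine signalling inhibitor gene Socs3 rose from 1.39 ± 0.138 to 31.1 ± 19.9 CPM (4.47 ± 0.53, edgeR adjusted p = 0.00615) and Ankrd1, a gene of stressed and denervated muscle, from 18.9 ± 6.9 to 316 ± 321 CPM (4.06 ± 0.67, 0.0141). Leptin (Lep), a gene of fat cells, fell from 19.1 ± 31.4 to 0.053 ± 0.0918 CPM (-8.19 ± 2.19, edgeR adjusted p = 0.0398). Young female 2 held 55.37 CPM of Lep, and without it the change was -3.87 (edgeR adjusted p = 0.216). Calls were lost in 6 of 6 fits for Lep, 4 for Oas2 and Cd68, 3 for C1qa and ND1, 1 for Gbp2 and Ankrd1 and 0 for Socs3. Of the mitochondrially encoded genes 4 of 13 fell (12 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation), ND1 being at -0.93 ± 0.20 (edgeR adjusted p = 0.0253). Summed over the macrophage list, old female 3 had 1624.5 CPM and old females 1 and 2 had 171.9 and 135.8. Over the interferon list the sums were 1229.1, 199.7 and 180.8 CPM. Timp1, an inhibitor of matrix proteases, was at 20.2 ± 33.8 CPM in old females. In total 945 genes passed (638 higher, 307 lower, edgeR). The count was 18, 68 and 201 without young female 1, 2 or 3 and 2589 and 81 without old female 1 or 3, and 113 with the library letter in the model.

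In male quadriceps, age changed 0 genes (edgeR; 2597 at an unadjusted p under 0.05, 503 by DESeq2, 1359 by limma voom). Averaged over the sexes 509 genes changed (280 higher, 229 lower), among them the cartilage matrix genes Comp (-2.20 ± 0.41, edgeR adjusted p = 0.0208; males 10.3 ± 5.44 to 1.67 ± 0.649 CPM) and Chad (-3.36 ± 0.70, 0.0283). The neutrophil protein gene S100a8 rose by 4.21 ± 0.90 (edgeR adjusted p = 0.0291), or 2.63 without female old 3. These calls were lost in 4 of 12 fits for Comp, 5 for Chad and 7 for S100a8. In males, of 23 genes of muscle denervation 0 passed over all genes (9 rose adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Chrnb1, an acetylcholine receptor subunit gene, was at 1.03 ± 0.23 (edgeR adjusted p = 0.0808). Of 11 satellite cell and Schwann cell markers 0 passed (6 fell adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), with Prx at -2.14 ± 0.40 (edgeR adjusted p = 0.0742). The sexes differed in the age effect for 32 genes (21 higher, 11 lower in females relative to males, edgeR), including the zinc finger gene Zc3h6 (-1.43 ± 0.19, adjusted p = 0.0117), which fell from 20.3 ± 0.315 to 10.6 ± 0.72 CPM in females, and the sphingolipid synthesis gene Sptssa (-1.10 ± 0.15, 0.0117), lost in 4 and 5 of 12 fits. The male count became 173 without old male 1. The averaged count was 77, 41 and 77 without male young 1, 2 or 3, 51 and 36 without male old 2 or 3, 74 and 125 without female young 1 or 2, and 2462 and 263 without female old 1 or 3. The sex-difference count was 1, 0 and 0 without male young 1, 2 or 3, 14, 0 and 4 without male old 1, 2 or 3, 0, 20 and 5 without female young 1, 2 or 3, and 244, 910 and 17 without female old 1, 2 or 3.

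Corylin changed 0 genes in quadriceps in males (edgeR; 1380 at an unadjusted p under 0.05, 78 by DESeq2, 50 by limma voom) and 0 in females (2467 at an unadjusted p under 0.05, 462 by DESeq2, 0 by limma voom). The genes with the smallest p in males were the glutathione synthesis gene Gclc, at 18.3 ± 2.63 CPM in corylin and 31.5 ± 1.73 in old males (-0.78 ± 0.13, edgeR adjusted p = 0.102), and the channel gene Pkd2, at 21.8 ± 3.8 and 12.9 ± 0.85 (0.75 ± 0.13, 0.11). In females they were Socs3 (-3 ± 0.48, edgeR adjusted p = 0.119) and Zc3h6 (0.83 ± 0.14, 0.119). Of 29 interferon-stimulated genes in females 0 passed over all genes (27 fell adjusted over the list alone; adjusted p = 0.397 with an estimated correlation). The interferon score was 3.515 in old female 3, 0.791 and 0.425 in old females 1 and 2, and -0.44 to 0.542 in corylin females. Of 11 satellite cell and Schwann cell markers in males 0 passed over all genes (7 rose adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), Pmp22 being at 1.15 ± 0.23 (edgeR adjusted p = 0.182). Slow fibre genes in males had 0 of 12 over all genes (8 rose adjusted over the list alone; adjusted p = 0.551 with an estimated correlation), and the slow myosin gene Myh7 was at 427 ± 718 CPM in corylin and 1.24 ± 1.27 in old males. The slow fibre score was 4 in corylin male 3, beside -1.189 and 0.248 in corylin males 1 and 2, and -1.769, -1.539 and -3.878 in old males 1, 2 and 3. The male count became 11, 3 and 2 without old male 3, corylin male 1 or corylin male 3. The female count became 1107 and 807 without old female 1 or 2. The averaged count of 0 (1131 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma voom) became 22 without female old 1. The sexes differed in the corylin effect for 0 genes (edgeR; 2790 at an unadjusted p under 0.05, 610 by DESeq2, 0 by limma voom), or 23, 301 and 572 without male corylin 1, female old 1 or female old 2.

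**Figure D1:**
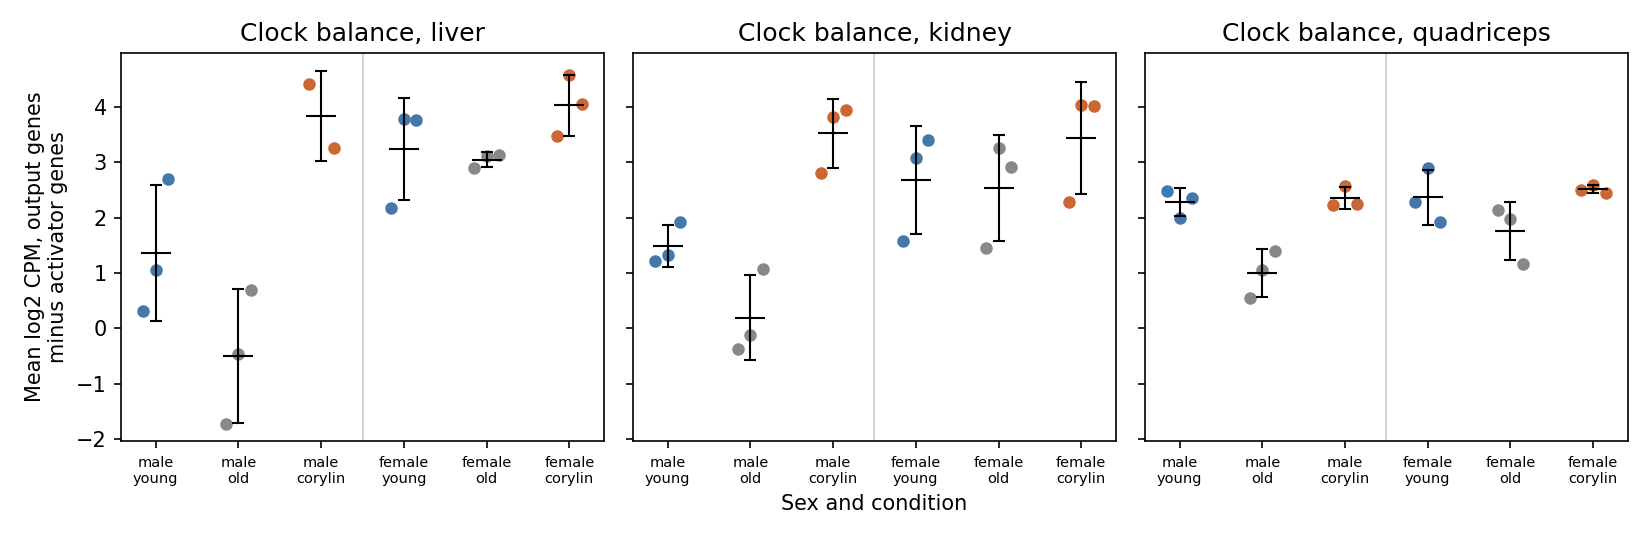
Clock balance of each library (y axis, mean log2 CPM of 10 output genes minus that of 5 activator genes) by sex and condition in liver, kidney and quadriceps, with points for libraries, and dashes and bars for mean and SD. Corylin males had means of 3.83 in liver, 3.52 in kidney and 2.35 in quadriceps against -0.49, 0.19 and 1 in old males. Young males were at 1.35, 1.49 and 2.28, and old males had the lowest mean of the groups in each tissue. The split of the clock list into these arms was chosen after its values were seen.

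**Figure D2:**
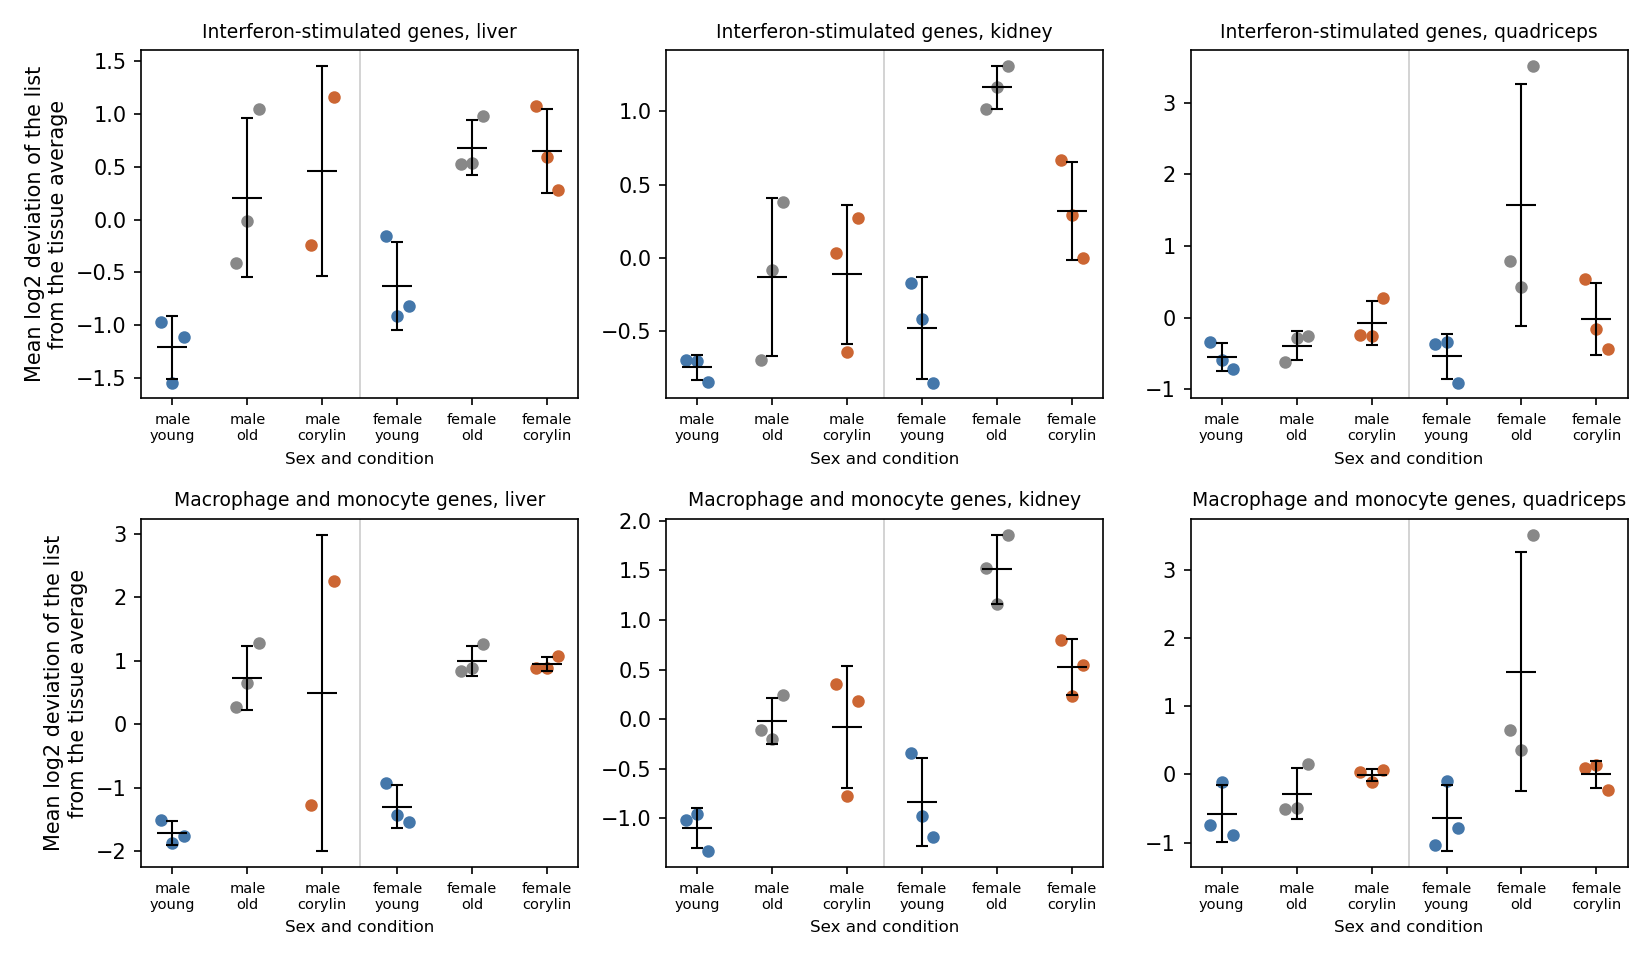
Scores of the interferon-stimulated and the macrophage and monocyte lists in each library (y axis, mean log2 deviation from the tissue average), by sex and condition in liver, kidney and quadriceps, with points for libraries, and dashes and bars for mean and SD. In quadriceps, old female 3 sits at 3.515 and 3.516, and old females 1 and 2 sit between 0.352 and 0.791.

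The corylin effect differed between liver, kidney and quadriceps for 38 genes (edgeR, over the genes kept in 1 fit of all tissues). Chka was at -1.32 ± 0.13 in liver, 0.08 ± 0.07 in kidney and -0.10 ± 0.26 in quadriceps (adjusted p for the difference 0.00236), Ginm1 at -0.99 ± 0.18, 0.02 ± 0.06 and 0.18 ± 0.08 (0.00236) and Clpx at -1.28 ± 0.22, -0.45 ± 0.10 and 0.11 ± 0.13 (0.00236). Insig2, a regulator of cholesterol synthesis chosen after its values were seen, was at -1.59 ± 0.28, -0.02 ± 0.06 and 0.14 ± 0.09 (0.00193). The count depended on many single libraries. Male corylin 2 is not the same animal in liver as in kidney and quadriceps. It was 13, 10, 338 and 16 without liver male old 1, old 2, corylin 2 or corylin 3. It was 23, 22, 125, 72, 23 and 19 without liver female old 1, old 2, old 3, corylin 1, corylin 2 or corylin 3. It was 19, 18, 19, 20 and 25 without kidney male old 1, old 2, old 3, corylin 2 or corylin 3. It was 61, 21 and 17 without kidney female old 3, corylin 2 or corylin 3. It was 15, 17, 20 and 21 without quadriceps male old 1, old 2, corylin 2 or corylin 3. It was 71, 22 and 22 without quadriceps female old 3, corylin 2 or corylin 3.

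Whether corylin moved genes against their change with age was asked by correlating both effects across genes, which are not independent replicates. Old libraries enter both effects with opposite sign, so unchanged groups also give a negative correlation, which was simulated. In females r was -0.425 in liver (simulated -0.507), -0.733 in kidney (-0.489) and -0.79 in quadriceps (-0.502), and in males 0.128 (-0.429), -0.367 (-0.492) and -0.537 (-0.498). The covariances in females were -0.308 in liver (simulated -0.105), -0.241 in kidney (-0.058) and -0.436 in quadriceps (-0.08), and in males 0.07 (-0.106), -0.075 (-0.062) and -0.159 (-0.084). With the old libraries split so that each effect had its own, the correlation averaged over the sexes was -0.099 in liver, -0.276 in kidney and -0.219 in quadriceps. One-sided permutation p over 1000 regroupings was 0.271, 0.032 and 0.059 (adjusted over the 3 tissues 0.271, 0.0885 and 0.0885). The regroupings exchange young with aged libraries too, so p cannot test opposition to age. The opposite values of C1qa and Slc7a13 in female kidney share the old females. Liver r in males was -0.636 without corylin male 3 and 0.331 without corylin male 2. In quadriceps r in females was -0.604 without old female 3.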

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

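The tests of normalization, collection time, lymphoid tissue, blood, the state of an animal, shared old libraries and a single library in this part, and the counts over other splits of the samples, were chosen after the results were seen. In kidney the corylin effect differed between the sexes for 1 gene, the cystine transporter gene Slc7a13 (edgeR), a count that was 5, 31 and 3 without male corylin 2, female old 3 or female corylin 1. Of 50 splits of the libraries 10 gave as many, so chance was not excluded, and the highest of the others, with 128 genes, relabelled female old 1 and 3 and female corylin 2 and 3, which points to a structure of the samples. The age effect differed between the sexes for 16 genes in kidney (edgeR), from 0 without male young 1 to 212 without female old 3, and in quadriceps for 32 (edgeR), from 0 without male young 2 to 910 without female old 2. In each, 3 of 50 splits gave as many. The highest of the other splits, 1522 genes in kidney and 509 in quadriceps, relabelled every young and old male, which turns the difference of the age effects into their sum, so this split is no test of chance. Without it, 2 of 49 gave as many in both tissues (highest other 820 in kidney, with male young 2 and 3 and male old 1 and 2 relabelled, and 156 in quadriceps, with female young 2 and female old 2 relabelled), several times the real counts. These splits too exchange young and old libraries within a sex and so mix the age effect into the difference, and whether chance is excluded stays open. Between liver, kidney and quadriceps the corylin effect differed for 38 genes (edgeR), from 10 without liver male old 2 to 338 without liver male corylin 2. The other splits gave at most 20, and 1 of 21, the real one, gave as many, a share under 0.05. It is the lowest share that 21 splits can give. Without liver male old 2 the real grouping gave 10, fewer than 20, so whether chance is excluded stays open. Among the 8 splits that kept the number of libraries of letter R per group, too few for such a share, the highest other was 0.

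In corylin males, output genes of the circadian clock were above their levels in old males and activators below, except 1 of 5 activators in quadriceps, where 0 genes passed (edgeR; 1380 at an unadjusted p under 0.05, 78 by DESeq2, 50 by limma voom), with gaps between the median log2 fold changes of 10 output and 5 activator genes of 4.23 in liver, 3.47 in kidney and 1.12 in quadriceps (SE of the gap of means 0.75, 0.65 and 0.44), beside 0.89, 0.93 and 0.70 in females (0.53, 0.18 and 0.27). The SEs are over genes, and the arms were split after their values were seen, so the gap cannot test normalization. A shift in the time of day at which an animal was collected would move its tissues together: deviations from the group means correlated between liver and kidney over 17 animals (r = 0.594, permutation p = 0.0138, adjusted over 3 pairs 0.0414; rho = 0.522, p = 0.0599, adjusted 0.18; r = 0.576 without the 2 farthest animals). They did not pass between liver and quadriceps over 17 animals (r = 0.302, permutation p = 0.324, adjusted 0.486; rho = 0.392, p = 0.188, adjusted 0.282; r = 0.165 without 2) or kidney and quadriceps over 18 (r = 0.067, permutation p = 0.844, adjusted 0.844; rho = 0.205, p = 0.507, adjusted 0.507; r = 0.043 without 2). Collection hours, which the labels do not give, and an effect of the corylin diet on the clock may each account for the gap and cannot be told apart, since a group collected at its own hour would differ in the same way. Old males had the lowest mean clock balance of the groups in each tissue. Young males were at 1.35 in liver, 1.49 in kidney and 2.28 in quadriceps, beside 3.83, 3.52 and 2.35 in corylin males. The gap thus also holds a departure of old males from the other groups.

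In quadriceps of old females, replicate 3 summed to 1624.5 CPM over the macrophage and monocyte list and 1229.1 over the interferon list, beside 171.9 and 199.7 in replicate 1 and 135.8 and 180.8 in replicate 2. Lymphoid tissue in the sample would bring T, NK, B and plasma cell transcripts, which summed to 118 CPM here and 472.4 and 381.7 in replicates 1 and 2. The T and NK list alone was at 13.9, beside 8.5 and 4.3 in replicates 1 and 2 and 2.4 to 14.7 in the other 15 libraries, and the B and plasma list at 104, beside 464 and 377.3. Blood would bring haemoglobin, which was 0.0193 percent of counts here and 0.0047 to 0.0285 in the other 17 quadriceps libraries, and 1.45 times the mean of the other old females where the neutrophil list was 27.3 times. A state of the whole animal, such as an infection, may show in its other organs, where its interferon score was 1.312 in kidney and 0.981 in liver, above the next old female by 0.147 and 0.443, but 3 animals are too few to tell this apart from an ordinary difference between animals. An inflammation of this muscle alone and a part in ageing that varies between animals also stay open and were not tested.

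Averaged over the sexes, the corylin and age effects in kidney were opposed across genes, with r = -0.548. Old libraries enter both effects with opposite sign, and with separate old libraries for each effect r was -0.276 (permutation p = 0.032, adjusted 0.0885). The regroupings mix young with aged libraries. Leaving out 1 library at a time gave -0.375 without female old 2 to -0.135 without female old 1. Shared old libraries and a single library may thus each hold part of the relation. A diet effect on genes that change with age also stays open.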

How the results depend on the processing

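The clock covariate, and leaving libraries out for gene lists, correlations and the difference between tissues, were alternatives chosen after seeing the data, and the others were planned. Single genes kept their direction in all 1704 values of named genes under other settings. Of these, 1265 stayed on their side of the threshold, 357 lost the call and 82 gained it, and of 98 called gene results 42 passed under every other setting and 35 without each library in turn. Counts are said to move where they changed by over 1.5 times, and correlations where they changed by more than the SD of their values without each library. The cause was not tested for any moved value, and each is given with the value of the planned edgeR or camera test in parentheses. Depth limits what can be said of genes left out by the low-count filter, such as Cdkn2a in kidney and quadriceps.

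With DESeq2, 23 of 27 counts moved, and of 126 named gene values 0 lost and 27 gained the call. DESeq2 called 131 (9) in liver males, 589 (23) in liver females, 760 (162) in liver on average, 82 (12) in kidney males, 226 (10) in kidney females, 114 (11) in kidney on average, 78 (0) in quadriceps males, 462 (0) in quadriceps females and 3 (0) in quadriceps on average for corylin against old. DESeq2 called 948 (32) in liver males, 2405 (1405) in liver females, 234 (19) in kidney males, 503 (0) in quadriceps males, 1597 (945) in quadriceps females and 1374 (509) in quadriceps on average for old against young. DESeq2 called 28 (0) in liver, 67 (1) in kidney and 610 (0) in quadriceps for the sex difference of the corylin effect. DESeq2 called 143 (0) in liver, 345 (16) in kidney and 733 (32) in quadriceps for the sex difference of the age effect. DESeq2 called 381 (194) in liver and 678 (170) in quadriceps for young females against males.

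With limma voom, 19 of 24 counts moved, and of 126 named gene values 20 lost and 16 gained the call. It called 0 (9) in liver males, 179 (23) in liver females, 1 (162) in liver on average, 77 (12) in kidney males, 134 (10) in kidney females, 33 (11) in kidney on average and 50 (0) in quadriceps males for corylin against old. It called 1262 (32) in liver males, 3490 (1405) in liver females, 4362 (2900) in liver on average, 1568 (19) in kidney males, 3340 (1522) in kidney on average, 1359 (0) in quadriceps males, 18 (945) in quadriceps females and 767 (509) in quadriceps on average for old against young. It called 20 (0) in liver, 554 (16) in kidney and 16 (32) in quadriceps for the sex difference of the age effect. It called 2 (1) in kidney for the sex difference of the corylin effect.

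Without the filter on low counts, 19 of 28 counts moved, and of 126 named gene values 24 lost and 3 gained the call. The unfiltered fit called 19 (9) in liver males, 53 (23) in liver females, 36 (10) in kidney females, 21 (11) in kidney on average and 1 (0) in quadriceps females for corylin against old. The unfiltered fit called 60 (32) in liver males, 793 (1405) in liver females, 64 (19) in kidney males, 7 (0) in quadriceps males, 402 (945) in quadriceps females and 309 (509) in quadriceps on average for old against young. The unfiltered fit called 1 (0) in liver, 9 (1) in kidney and 13 (0) in quadriceps for the sex difference of the corylin effect. The unfiltered fit called 12 (0) in liver, 81 (16) in kidney and 54 (32) in quadriceps for the sex difference of the age effect. The unfiltered fit called 71 (170) in quadriceps for young females against males. The unfiltered fit called 23 (38) for the difference of the corylin effect between tissues.

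With only the groups compared in the fit, 15 of 24 counts moved, and of 123 named gene values 43 lost and 8 gained the call. The smaller fits called 0 (9) in liver males, 0 (23) in liver females, 4 (162) in liver on average, 0 (10) in kidney females, 0 (11) in kidney on average and 4 (0) in quadriceps males for corylin against old. The smaller fits called 1282 (32) in liver males, 232 (19) in kidney males, 677 (1863) in kidney females, 664 (0) in quadriceps males, 1 (945) in quadriceps females and 33 (509) in quadriceps on average for old against young. The smaller fits called 2 (0) in liver for the sex difference of the corylin effect. The smaller fits called 20 (0) in liver and 8 (32) in quadriceps for the sex difference of the age effect.

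With the library letter in the model, 14 of 24 counts moved, and of 126 named gene values 15 lost and 6 gained the call. This model called 15 (9) in liver males, 146 (23) in liver females, 246 (162) in liver on average, 23 (12) in kidney males, 31 (10) in kidney females and 25 (11) in kidney on average for corylin against old. This model called 21 (32) in liver males, 2 (19) in kidney males, 2 (0) in quadriceps males, 113 (945) in quadriceps females and 57 (509) in quadriceps on average for old against young. This model called 41 (0) in liver and 75 (16) in kidney for the sex difference of the age effect. This model called 4 (1) in kidney for the sex difference of the corylin effect.

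With median-of-ratios scaling, 1 of 37 counts and correlations moved, and of 126 named gene values 0 lost and 0 gained the call. This scaling called 19 (11) in kidney on average for corylin against old.

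A replicate block, the replicate number as a factor, moved 10 of 45 values, and of 126 named gene values 5 lost and 2 gained the call. The blocked fit called 58 (32) in liver males, 44 (19) in kidney males and 833 (509) in quadriceps on average for old against young. The blocked fit called 20 (0) in liver, 132 (16) in kidney and 18 (32) in quadriceps for the sex difference of the age effect. The blocked fit called 30 (12) in kidney males, 51 (10) in kidney females and 40 (11) in kidney on average for corylin against old. The blocked fit called 2 (1) in kidney for the sex difference of the corylin effect. It moved no other count, of genes or of lists. The numbers did not pair the libraries: of 35 pairs of libraries with the same number in the groups compared, 9 had a correlation of their deviations over 0.1 (range -0.251 to 0.482), and no comparison with 3 pairs had each of them over 0.1. Corylin and old males in liver had 2 pairs, both over it (0.312 and 0.482). The median was 0.027, against -0.0235 for other pairs.

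The number of called gene lists was lower with an estimated correlation in each comparison. Camera then called 0 (13) in liver males, 0 (21) in liver females, 0 (17) in liver on average, 0 (5) in kidney males, 0 (22) in kidney females, 0 (24) in kidney on average, 0 (16) in quadriceps males, 0 (19) in quadriceps females and 0 (23) in quadriceps on average for corylin against old. Camera then called 0 (27) in liver males, 0 (23) in liver females, 0 (27) in liver on average, 1 (24) in kidney males, 6 (25) in kidney females, 6 (25) in kidney on average, 0 (16) in quadriceps males, 0 (18) in quadriceps females and 0 (21) in quadriceps on average for old against young. The self-contained test fry moved 15 of 18 list counts. Fry called 0 (13) in liver males, 0 (21) in liver females, 0 (17) in liver on average, 0 (5) in kidney males, 4 (22) in kidney females, 0 (24) in kidney on average, 1 (16) in quadriceps males, 0 (19) in quadriceps females and 0 (23) in quadriceps on average for corylin against old. Fry called 11 (27) in liver males, 12 (23) in liver females, 2 (24) in kidney males, 6 (16) in quadriceps males, 9 (18) in quadriceps females and 9 (21) in quadriceps on average for old against young.

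The correlation of the corylin and age effects, over the genes changed with age alone, was -0.646 (0.128) in liver males, -0.768 (-0.425) in liver females, -0.593 (-0.367) in kidney males, -0.885 (-0.733) in kidney females, -0.766 (-0.548) in kidney on average, -0.944 (-0.79) in quadriceps females and -0.855 (-0.693) in quadriceps on average. Male quadriceps had no such genes and gives no value. Choosing genes by an age effect that holds the same old libraries can by itself lower this correlation, and no value for unchanged groups was computed over such genes, so the lower values show no stronger relation. With separate old libraries for each effect it was -0.276 (-0.548) in kidney on average and -0.219 (-0.693) in quadriceps on average. With a clock covariate corylin against old gave 0 (9) in liver males and 0 (12) in kidney males. Clock balance did not overlap between these groups (liver 3.254 to 4.409 in corylin and -1.714 to 0.696 in old males, kidney 2.806 to 3.931 and -0.365 to 1.073). The covariate was not checked for this, so the lost calls leave stability open. Without the animal block the corylin effect differed between tissues for 62 (38) genes.

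Leaving out each library in turn moved 188 of 514 values, given as the lowest and highest per result. Changed genes for corylin against old numbered 4 to 1533 in liver males, 0 to 543 in liver females, 30 to 1582 in liver on average, 2 to 11 in kidney males, 2 to 117 in kidney females, 4 to 38 in kidney on average, 0 to 11 in quadriceps males, 0 to 1107 in quadriceps females and 0 to 22 in quadriceps on average. Changed genes for old against young numbered 0 to 39 in liver males, 256 to 1531 in liver females, 1700 to 2861 in liver on average, 1 to 30 in kidney males, 1034 to 2260 in kidney females, 0 to 173 in quadriceps males, 18 to 2589 in quadriceps females and 36 to 2462 in quadriceps on average. Changed genes for the sex difference of the corylin effect numbered 0 to 519 in liver, 1 to 31 in kidney and 0 to 572 in quadriceps. Changed genes for the sex difference of the age effect numbered 0 to 27 in liver, 0 to 212 in kidney and 0 to 910 in quadriceps. Changed genes for young females against males numbered 92 to 138 in liver, 572 to 826 in kidney and 12 to 194 in quadriceps. Called lists for corylin against old numbered 11 to 21 in liver males, 9 to 14 in kidney males, 10 to 16 in quadriceps males and 12 to 27 in quadriceps on average. The correlation of the corylin with the age effect ranged over -0.636 to 0.331 in liver males, -0.523 to -0.339 in liver females, -0.607 to 0.15 in liver on average, -0.474 to -0.241 in kidney males, -0.782 to -0.649 in kidney females, -0.618 to -0.45 in kidney on average, -0.634 to -0.471 in quadriceps males, -0.859 to -0.604 in quadriceps females and -0.79 to -0.531 in quadriceps on average. The count of genes whose corylin effect differed between tissues ranged over 10 to 338. With 1 library left in liver of corylin males, the lone sample is assumed to vary like the other groups.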

Other observations

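The counts over other splits of the samples in this part were chosen after the results were seen, and the gene list tests were planned. In old male liver, interferon-stimulated genes had 0 of 32 past the threshold over all genes and 26 that rose and 0 that fell adjusted over the list alone (adjusted p = 0.289 with an estimated correlation), with Irf7 at 2.26 ± 0.49 and Gbp3 at 2.35 ± 0.54 (edgeR adjusted p = 0.079 for both). Of 24 macrophage and monocyte markers 1 rose over all genes and 22 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). The lysozyme gene Lyz2 was at 3.22 ± 0.64 and Trem2, a receptor of lipid-laden macrophages, at 5.39 ± 1.24 (edgeR adjusted p = 0.0649 and 0.079). Nuclear genes of oxidative phosphorylation had 0 of 58 over all genes and 37 that fell adjusted over the list alone (adjusted p = 0.293 with an estimated correlation), Ndufb10 being at -0.68 ± 0.17 (edgeR adjusted p = 0.087). In old female liver, 7 of 22 immediate early genes rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation), among them Ier3 at 3.43 ± 0.49 and the AP-1 subunit gene Fosl2 at 2.27 ± 0.41 (edgeR adjusted p = 0.00387 and 0.00859). Of 15 lipid droplet and lipid storage genes 3 fell and 0 rose (8 fell and 2 rose adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). They included the lipoprotein receptor gene Vldlr at -3.27 ± 0.62 and the perilipin gene Plin4 at -3.20 ± 0.77 (edgeR adjusted p = 0.0101 and 0.0253), the call of Plin4 being lost in 5 of 6 fits without 1 library. In liver of corylin females, markers of B and plasma cells had 0 of 20 over all genes and 12 that rose and 2 that fell adjusted over the list alone (adjusted p = 0.596 with an estimated correlation). The B cell factor gene Pax5 was at 4.45 ± 1.13 and the immunoglobulin gene Ighg2c at -5.98 ± 1.09 (edgeR adjusted p = 0.0975 and 0.0507). Neutrophil markers had 0 of 12 over all genes and 8 that fell adjusted over the list alone (adjusted p = 0.482 with an estimated correlation).

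Old female kidney also showed rises of dividing cell, podocyte, stress and lymphocyte genes. Of 31 cell cycle genes 8 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation), with Cdk1 at 2.36 ± 0.47 and Mki67 at 1.79 ± 0.40 (edgeR adjusted p = 0.00395 and 0.0078). Markers of podocytes, the filter cells of the glomerulus, rose in 5 of 11 cases (8 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation), Synpo by 0.84 ± 0.16 (edgeR adjusted p = 0.00307). Genes of the unfolded protein and integrated stress response rose in 10 of 26 cases (15 adjusted over the list alone; adjusted p = 0.156 with an estimated correlation), with Atf3 at 2.12 ± 0.32 and Xbp1 at 0.92 ± 0.20 (edgeR adjusted p = 0.00057 and 0.00588). T and NK cell markers rose in 10 of 22 cases (15 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with Nkg7 at 1.86 ± 0.33 and the granzyme gene Gzmk at 2.74 ± 0.49 (edgeR adjusted p = 0.00166 and 0.00174). In male kidney 0 of these 22 passed over all genes and 12 rose adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). Of 25 cholesterol synthesis genes 5 rose in old female kidney (6 adjusted over the list alone; adjusted p = 0.472 with an estimated correlation). In old female quadriceps 4 of 18 heat shock genes rose (6 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation), the small heat shock protein gene Hspb8 by 0.95 ± 0.21 and Hsp90aa1 by 0.90 ± 0.19 (edgeR adjusted p = 0.025 for both, each lost in 4 of 6 fits without 1 library). In quadriceps of corylin females, extracellular matrix genes had 0 of 33 over all genes and 23 that fell adjusted over the list alone (adjusted p = 0.397 with an estimated correlation), with biglycan (Bgn) at -1.43 ± 0.34 (edgeR adjusted p = 0.119), or -0.70 without old female 3. The matrix score of old female 3 was 2.06, beside 0.418 and -0.045 in old females 1 and 2. Immediate early genes had 0 of 22 there, and 14 that fell adjusted over the list alone (adjusted p = 0.397 with an estimated correlation), with Egr1 at -1.96 ± 0.53 (edgeR adjusted p = 0.119). In old male quadriceps the matrix list had 0 of 33 over all genes and 15 that fell adjusted over the list alone (adjusted p = 0.443 with an estimated correlation), with Col15a1 at -2 ± 0.45 (edgeR adjusted p = 0.0808).

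For comparisons of 3 libraries against 3, the 10 splits of the samples are too few for a share under 0.05, and the real count is given with the highest of the other splits in parentheses. In liver, changed genes numbered 32 (0) for age in males, 1405 (0) for age in females, 194 (0) for sex in young mice and 23 (244) for corylin in females. In kidney they numbered 19 (0) for age in males, 1863 (1) for age in females, 1073 (0) for sex in young mice, 12 (0) for corylin in males and 10 (108) for corylin in females. In quadriceps they numbered 0 (0) for age in males, 945 (281) for age in females, 170 (0) for sex in young mice, and 0 (0) for corylin in males and in females (edgeR; the counts of 0 had 2597, 1380 and 2467 genes at an unadjusted p under 0.05, 503, 78 and 462 by DESeq2, and 1359, 50 and 0 by limma voom). The splits with 244 genes in liver and 108 in kidney both relabelled old female 3 and corylin female 1, and each called several times the real count, which points to a structure of the samples. Each put both libraries with the letter R, old female 3 and corylin female 3, in the same group, where the real groups hold 1 each. With the letter in the model the real comparison gave 146 genes in liver and 31 in kidney. Among the 6 splits that kept 1 such library per group, the highest other was 0 in liver and 40 in kidney. The split with 281 genes in quadriceps relabelled young female 3 and old female 1. Called gene lists numbered 27 (26) for age in male liver, 23 (19) for age in female liver, 21 (17) for corylin in female liver, 24 (20) for age in male kidney and 25 (26) for age in female kidney. They numbered 5 (27) for corylin in male kidney, where the other splits again called several times the real count, and 22 (21) for corylin in female kidney. In quadriceps they numbered 16 (16) for age in males, 18 (23) for age in females, 16 (18; 10 without old male 2) for corylin in males and 19 (21) for corylin in females.

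Comparisons averaged over the sexes were set against 50 splits. Chance was excluded for the age counts, where only the real split gave as many in each tissue. Liver gave 2900 genes (highest other 17) and kidney 1522 (702, with male young 1 and male old 1 exchanged). Quadriceps gave 509 (32, the sex difference, with every male relabelled), or 57 with the letter in the model. For corylin in liver, 2 of 50 splits gave the 162 genes or more, a share under 0.05. The other, which relabelled male old 3, male corylin 2, female old 3 and female corylin 2, called 857, several times the real count, which points to a structure of the samples. It put all 4 libraries with the letter R on the corylin side, where the real groups hold 1 each, so the splits mix the letter with the grouping. With the letter in the model the count was 246, and among the 17 splits that kept 1 such library per group, too few for a share under 0.05, the highest other was 4. Chance was not excluded for corylin in kidney, where 4 of 50 splits gave the 11 genes or more (25 with the letter in the model). The highest other, 128, relabelled every old and corylin male and so gives a sex difference. In quadriceps the edgeR count of 0 leaves nothing to test (highest other 1). At an unadjusted p under 0.05 it had 1131 genes, with 3 by DESeq2 and 0 by limma voom. For the sex difference, the real count was 0, which any of the 50 splits reaches, in liver for age (highest other 2900, with every young and old male relabelled) and for corylin (70), and in quadriceps for corylin (4), by edgeR. At an unadjusted p under 0.05 these had 1307, 1033 and 2790 genes, with 143, 28 and 610 by DESeq2 and 20, 0 and 0 by limma voom. Of called gene lists, 2 of 50 splits gave the 27 for age in liver (highest other 28). The count was 24 without female old 3, so chance stays open. For the 23 for corylin in quadriceps 2 of 50 splits gave as many (highest other 23), a share under 0.05, but the 20 splits that kept 1 library of letter R per group are too few for such a share, and their highest other was 23 as well. With an estimated correlation 0 lists were called in both, and fry called 28 for age in liver and 0 for corylin in quadriceps. The count of 23 was 12 without female old 3. Chance was not excluded for corylin in liver (17 lists, 28 splits, highest other 28), age in kidney (25 lists, 7 splits, 27), corylin in kidney (24 lists, 8 splits, 31) or age in quadriceps (21 lists, 13 splits, 24).

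The correlation of the corylin with the age effect was set against 100 regroupings of the young, old and corylin libraries, the real one included. These mix age into both effects, and chance stays open for all 8. In females 61 regroupings were as low as the real -0.425 in liver (lowest other -0.788), 5 as low as -0.733 in kidney (-0.802) and 13 as low as -0.79 in quadriceps (-0.865). In males 87 were as low as -0.367 in kidney (-0.753) and 42 as low as -0.537 in quadriceps (-0.797). Averaged over the sexes 88 were as low as -0.059 in liver (-0.872), 41 as low as -0.548 in kidney (-0.74) and 17 as low as -0.693 in quadriceps (-0.838).

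The authors' deposited table, at an adjusted p under 0.05, called 133 genes for corylin against old in liver of males (55 up, 78 down) and 572 of females (238 up, 334 down). It held 84 (26 up, 58 down) and 204 (56 up, 148 down) in kidney and 71 (48 up, 23 down) and 466 (86 up, 380 down) in quadriceps, per the authors' deposited table. For old against young, the authors' deposited table called 947 and 2376 genes in liver of males and females, 222 and 2304 in kidney, and 495 and 1637 in quadriceps.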
